A study of Mus musculus with 8 samples.

How the data were processed

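Gene expression was measured in B16F0 mouse melanoma cells and in the exosomes isolated from medium conditioned by them, with 4 samples of each and 1 Affymetrix mouse exon array per sample. Per the labels' protocols, total RNA was isolated with a column kit, converted to cDNA with a whole-transcript kit, and an equal mass of cDNA was fragmented, labelled with biotin and hybridised for each sample. Levels are therefore relative to the RNA put on each array, not amounts per cell or per vesicle. How the exosomes were isolated, and whether their RNA was treated to remove RNA outside vesicles, is not given in the sources used here.

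The deposited values were on a log2 scale, with a range from 0.65 to 14.1 over all arrays. Per the submitters' processing notes, the authors used Affymetrix Expression Console with RMA, a method that corrects background, normalizes and summarizes probes, and the genome build mm8. Versions and settings are not given in the sources used here. Per the series text, the authors averaged the core probesets of a gene. The arrays of cells and exosomes did not share a common distribution, since their quartiles differed, so the scale between the groups is that of the deposited values and was varied as an alternative. No depth exists for arrays. Signal over background took its place, measured as the 75th percentile of an array minus the median of its background genes, which was 4.91 ± 0.08 in cells and 2.92 ± 0.09 in exosomes (SD, n = 4 each).

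Genes were named through the platform table given with the data. Of 23332 transcript clusters, 14996 had 1 gene symbol, 1019 had several and 7317 were unnamed here. Of those with 1 symbol, 14941 matched a RefSeq table of assembly GRCm38.p6 by gene identifier, all with the same symbol. That table gave gene lengths only, and no coordinates were used, because its assembly differs from that of the submitters. For 135 genes with more than 1 transcript cluster, the cluster with the highest mean over all 8 arrays stood for the gene, and for 10 of these genes the clusters were called in opposite directions.

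Groups were compared with limma (version 3.58.1 in R 4.3.3), using lmFit and eBayes on the log2 values, two-sided, with Benjamini-Hochberg adjustment over all transcript clusters, calls at an adjusted p below 0.05 and no filter on dim signals. A second count required a change of at least 2-fold. The labels give both groups the replicate numbers 1 to 4 without saying that a number marks a shared culture, so no block was used. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over 31 of 35 lists that had at least 5 measured members. Each list was also tested with an estimated correlation, and its median was placed among those of 10000 random lists of the same size matched on mean level over all arrays, since dim genes have little room to fall. Camera compares a list with all other genes, whose median log2 fold change was -0.39. A gene was above background in a group when it exceeded the 95th percentile of the chemosensory receptor genes of the same array on all 4 arrays. This rule replaced the authors' comparison with negative control probesets, whose values were not used here. A gene not above background on any exosome array was given as a bound, the mean of the cells against the mean background threshold of the exosome arrays. Folds are powers of 2 of differences between mean log2 values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

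The groups, tests, gene lists, most alternatives and the rule for named genes were set before the data were examined. The rule took the 12 largest rises and the 12 largest falls among called genes of known name whose groups did not overlap and which were above background in the higher group. It also took 12 fixed genes, namely the phosphatase gene Ptpn11 and genes of pigment cells, exosomes and common controls. From each list it took up to 4 called members in the direction of the list's median with 1 against it. Exceptions are marked where they occur.

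The steps were tested on simulated data of 23332 transcript clusters for exosomes against cells. Of 50 clusters changed at each size, 30% were recovered at a log2 change of 0.5, 64% at 1, 90% at 2 and 96% at 3, and 5 of 23099 unchanged clusters were called. The only list called of 31 was the one that had been shifted. Clusters were drawn independently of each other, and the groups had alike distributions apart from these changes. The simulation therefore does not measure false list calls where genes are correlated or array distributions differ. No 2 arrays held identical values. Alternatives were quantile normalization, cyclic loess, centring on background genes, a filter on dim signals, a trended and robust prior, array weights, the replicate number as a block, stricter thresholds, other background rules and leaving out each array in turn.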

Results

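The data came from B16F0 cells, a mouse melanoma line that makes pigment, and from the exosomes they released, which are small membrane vesicles that carry RNA and protein out of cells. Total RNA from 4 samples of cells and from 4 samples of exosomes, each taken after 24 h of culture without serum, was hybridised to whole-transcript exon arrays, 1 array per sample. The deposited log2 values covered 23332 transcript clusters, of which 14996 carried 1 gene symbol and stood for 14860 genes. The upper range of values was lower on the exosome arrays, with a 75th percentile of 8.53 ± 0.06 in cells and 7.13 ± 0.06 in exosomes (mean ± SD, n = 4 each). Chemosensory receptor genes, which encode odour, pheromone and taste receptors and stood in for background here, were higher on the exosome arrays, with a median of 3.62 ± 0.05 in cells and 4.21 ± 0.08 in exosomes (n = 4 each). For both measures all 4 exosome arrays lay on the same side of all 4 cell arrays (exact permutation p = 0.0286, two-sided, the smallest that 4 arrays against 4 allow). The labels do not say that samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

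The first comparison asked which mRNAs were found in cells and which in exosomes. By the rule set in advance, nearly all genes above background in exosomes were also above background in cells, while many genes of the cells were not above background in exosomes. Of the pigmentation genes, which make and sort melanin, 19 of 21 measured members were above background in cells and 19 in exosomes. Endoplasmic reticulum chaperones, which fold secreted proteins, were above background for 25 of 25 members in cells and 24 in exosomes. Interferon response genes, which act against viruses, were above background for 18 of 21 members in cells and 2 in exosomes. For mitochondrial ribosomal proteins the numbers were 66 of 68 in cells and 34 in exosomes. For S phase genes, which serve DNA replication, they were 37 of 37 and 18. The background threshold was higher in exosomes (log2 6.49 against 5.74), so these counts depend on the level in cells. Median cell levels were 11.49 for pigmentation, 11.34 for chaperone, 8.55 for mitochondrial ribosomal, 8.42 for S phase and 7.14 for interferon genes. All 25 chaperones fell (median log2 fold change -2.32), yet 24 stayed above background. Of all genes above background in cells, 56.5% were so in exosomes. The counts alone thus do not show selective loss.

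Among 14019 genes other than the background genes, 9143 were above background on all 4 cell arrays and 5173 on all 4 exosome arrays. The sets shared 5167 genes, against 3374 for independent sets of these sizes, so 99.9% of the exosome genes were also above background in cells and 56.5% of the cell genes in exosomes. The 6 genes of the exosome set outside the cell set were Mdk, which encodes the growth factor midkine, and 4930451I11Rik, A3galt2, D17Ertd663e, Hus1b and Kcnj14, named after their values were seen. All 6 were called higher by limma, among them D17Ertd663e by 6.25-fold (log2 fold change 2.64 ± 0.12 SE) with 3 of 4 cell arrays above background, and Mdk by 1.99-fold (0.99 ± 0.08) with 2 of 4. There were 0 genes above background on all 4 exosome arrays and on no cell array. The 7317 transcript clusters unnamed here were not part of these counts. These shares depended on the background rule: by the test that the series text names, applied to the background genes in place of control probesets at its stricter limit, 982 of 1949 exosome genes, or 50.4%, were also above background in cells. Of the 967 others, 788 exceeded the 95th percentile of background genes on all cell arrays. The 2785 genes above background on all cell arrays and on no exosome array included Cd9, Selenok, Tmed5 and Pqlc3, and 2356 of them were called lower in exosomes. The background threshold itself was higher on the exosome arrays, at 6.49 ± 0.06 against 5.74 ± 0.03 on the cell arrays (SD, n = 4 each). Across all transcript clusters the mean levels of the groups correlated with r = 0.897 and rho = 0.912, beside r of 0.987 to 0.991 between cell arrays and 0.975 to 0.978 between exosome arrays. These are correlations across genes, which are not independent replicates, and r fell to 0.702 when only transcript clusters above background in a group were used.

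The second comparison asked which mRNAs were higher or lower in exosomes than in the cells that released them. With 1 transcript cluster standing for each gene, the largest rise was that of Cmtm4, which encodes a membrane protein of the MARVEL family, at 15.3-fold (log2 fold change 3.93 ± 0.07 SE, n = 4 arrays per group, limma adjusted p = 2.65e-08). Sec22c, a protein of vesicle transport between endoplasmic reticulum and Golgi, rose 13.4-fold (3.74 ± 0.10), and Kif1c, a kinesin motor that moves vesicles along microtubules, rose 13.0-fold (3.70 ± 0.07). Mafg, a small Maf transcription factor, rose 10.5-fold, Crebl2, a leucine zipper protein, 8.76-fold, and Dnmt3a, a DNA methyltransferase, 8.54-fold. Tbc1d16, which switches off Rab GTPases, rose 8.83-fold, and Rdh10, a retinol dehydrogenase, 8.10-fold. The other genes among the 12 largest rises were Antkmt at 10.8-fold, Metrn at 10.4-fold, Fam32a at 9.08-fold and Asb1 at 8.88-fold. For each of the 12 genes all 4 exosome values lay above all 4 cell values. A second transcript cluster of Kif1c, which did not stand for the gene, had a larger log2 fold change of 4.24.

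Among the 12 genes with the largest falls, Lgals3bp fell most of those above background in both groups, by 31.6-fold (log2 fold change -4.98 ± 0.12 SE, n = 4 arrays per group, limma adjusted p = 2.71e-08). Lgals3bp encodes a secreted glycoprotein that binds galectins. Asah1, the lysosomal acid ceramidase, fell 22.6-fold (-4.50 ± 0.13), and Serinc1, a membrane protein, fell 19.6-fold (-4.30 ± 0.12). The other 9 of the 12 largest falls were not above background on any exosome array, so their folds are bounds against the background threshold of the exosome arrays. Pqlc3 was at least 18.3-fold lower, and Tcea1, a transcription elongation factor, at least 12.3-fold lower. Spcs1, a subunit of the signal peptidase complex, was at least 7.64-fold lower, and Tmed5, a cargo protein of the early secretory pathway, at least 6.90-fold lower. Selenok, a selenoprotein of the endoplasmic reticulum, was at least 4.18-fold lower, Tmx3, a thioredoxin-like protein of the same compartment, at least 4.05-fold lower, and Supt4a, Cenpq and Slbp at least 2.79-fold, 2.44-fold and 1.07-fold lower.

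**Figure D1:**
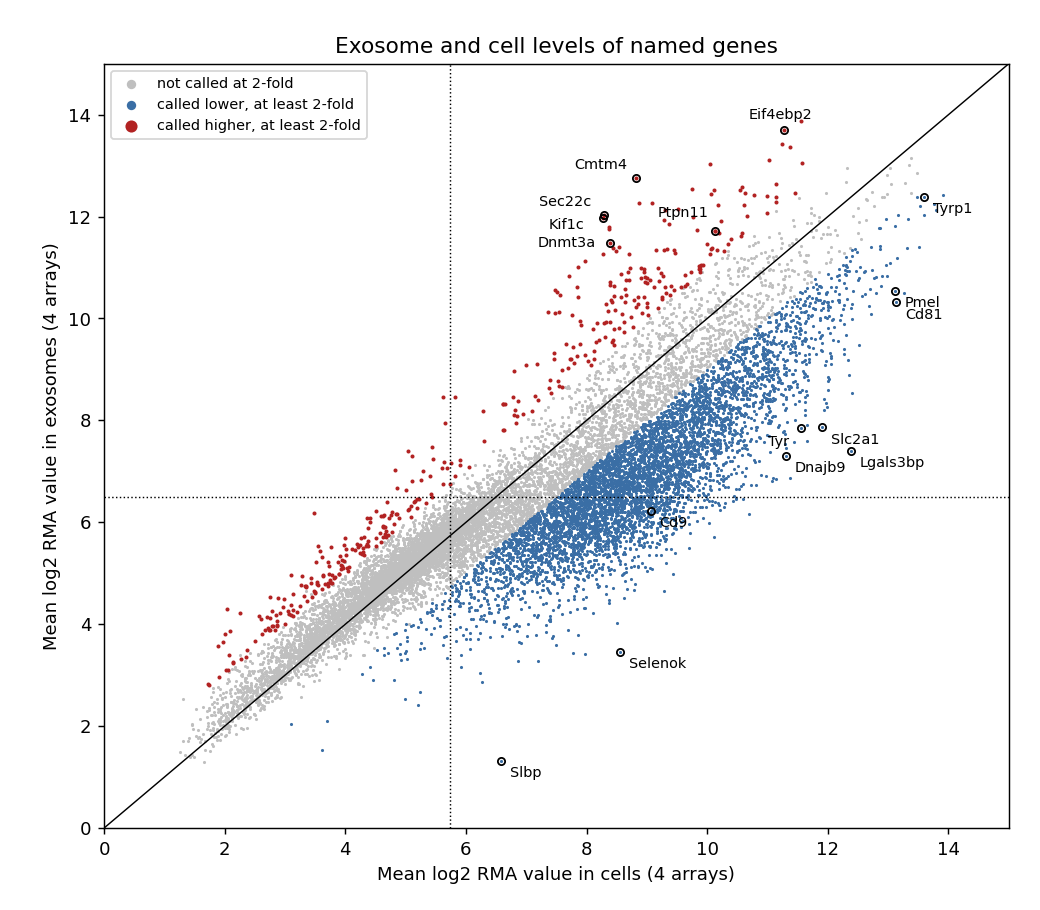
Mean log2 RMA value of each named gene in exosomes (vertical axis) against cells (horizontal axis), 4 arrays each, with genes called at a 2-fold change in colour, equal levels as a solid line and the mean background thresholds as dotted lines. Cmtm4, Sec22c and Kif1c lie far above the line, at 15.3-fold, 13.4-fold and 13.0-fold, and Lgals3bp lies 31.6-fold below it.

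In all, limma called 13826 of 23332 transcript clusters, 3818 higher and 10008 lower in exosomes. Of these, 8523 changed at least 2-fold, 1268 higher and 7255 lower. The 13826 calls included 3270 of clusters unnamed here, 1444 higher and 1826 lower. With 1 cluster for each of 14860 genes, 9903 were called, 2165 higher and 7738 lower. The values of the groups did not overlap for 13165 transcript clusters, or 56.4%, where chance gives 2 in 70. Among the 5167 genes above background in both groups, 195 rose and 2882 fell at least 2-fold, and the median log2 fold change was -1.16. The split between rises and falls depended on the scaling of the arrays. Calls were 27.6% higher as deposited and 50.2% after quantile normalization (6627 higher, 6582 lower). They were 51.2% higher after cyclic loess (6799 and 6490) and 6.00% after centring on background genes (1062 and 16646). At 2-fold, 2783 were higher and 3448 lower after quantile normalization. The 2-fold counts were 2833 and 2915 after cyclic loess, and 526 and 10107 after centring on background genes. The median log2 fold change of all transcript clusters was -0.20 as deposited, 0.05 after quantile normalization, 0.03 after cyclic loess and -0.79 after centring on background genes. All 195 genes that rose at least 2-fold were called higher under each of these scalings. Centring on background genes lowered exosome values relative to cell values by 0.59, less than the log2 limit of 1 that chose these genes.

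Among the genes chosen in advance, Ptpn11 rose and the pigment genes and tetraspanins fell. Ptpn11, which encodes a tyrosine phosphatase of cytokine and growth factor signalling, rose 2.99-fold (log2 fold change 1.58 ± 0.06 SE, n = 4 arrays per group, limma adjusted p = 1.09e-07). Tyr, the enzyme that starts melanin synthesis, fell 13.0-fold (-3.70 ± 0.15), and Pmel, the fibril protein of the melanosome, fell 5.96-fold (-2.58 ± 0.06). Dct and Tyrp1, further enzymes of melanin synthesis, fell 3.13-fold and 2.30-fold, and Mitf, the transcription factor that drives pigment genes, 2.65-fold. Of 141 genes with a mean log2 value above 12 in cells, 137 were called lower, with a median log2 fold change of -1.54. Among such bright genes, Tyrp1 (-1.20) and Mitf (-1.41) fell less than this median, Dct (-1.65) slightly more and Pmel more. In exosomes, Tyrp1 and Dct still had mean log2 values of 12.39 ± 0.05 and 12.14 ± 0.06 (SD, n = 4). Cd81, a tetraspanin of exosome membranes, fell 7.06-fold (-2.82 ± 0.08), and Cd9, a related tetraspanin, was at least 5.94-fold lower and not above background in exosomes. Actb, which encodes cytoplasmic actin, fell 2.97-fold (-1.57 ± 0.09). All of these directions held under each scaling. Mlana, Cd63 and Gapdh had no transcript cluster with a single gene symbol and were not analysed here.

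**Figure D2:**
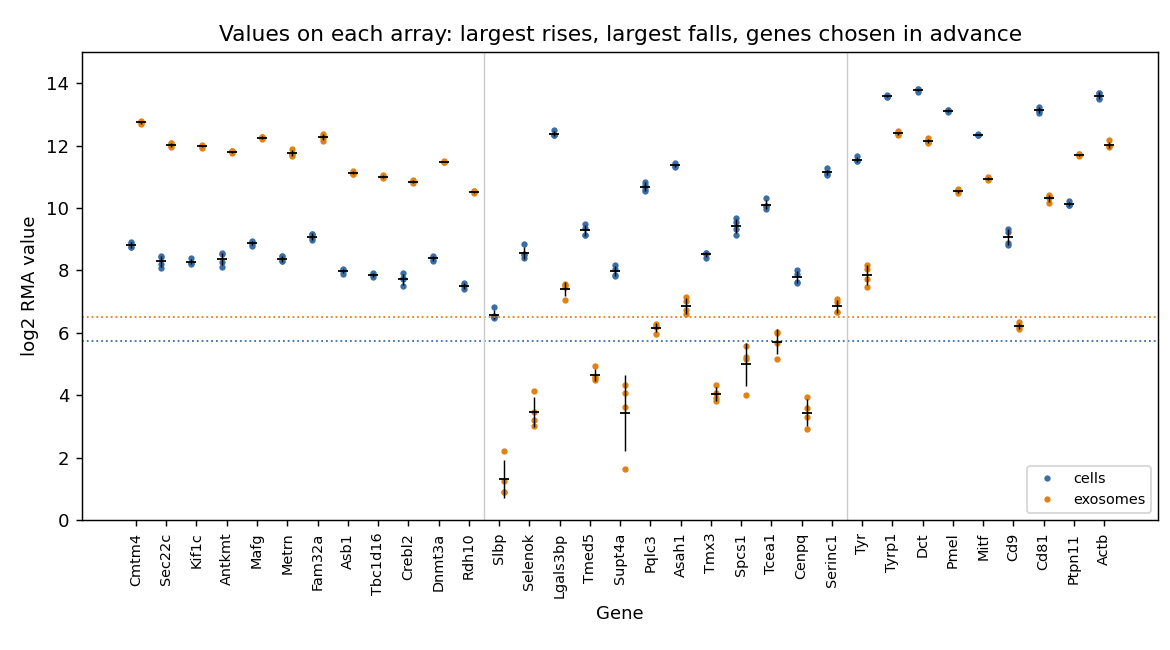
Log2 RMA values on each array (points, 4 cell and 4 exosome arrays per gene) with mean and SD (black bars) for the 12 largest rises, the 12 largest falls and the genes chosen in advance, with the mean background threshold of each group as a dotted line. Cell and exosome values did not overlap for any gene shown, and Ptpn11 was the only gene chosen in advance that was higher in exosomes, by 2.99-fold.

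In 7 gene lists the fall was called under each scaling and also among genes above background in both groups alone, a restriction chosen after the results were seen. Under that restriction the camera adjusted p was 0.0138 for the chaperones and 0.0228 for the proteasome. The rest of the 7 passed narrowly, with adjusted p from 0.0447 to 0.0454. With an estimated correlation none of the 7 was called (adjusted p = 0.281 with an estimated correlation for each). All 25 chaperones and unfolded protein response genes of the endoplasmic reticulum fell (median log2 fold change -2.32, limma camera adjusted p = 3.86e-06), with Dnajb9 15.9-fold, Pdia4 9.46-fold and Hsp90b1 8.87-fold lower. Of 33 proteasome subunits 30 fell (median -1.89, adjusted p = 1.47e-05), such as Psma6 at 9.19-fold and Psma2 at 8.54-fold, and 31 fell when adjusted over the list alone. All 12 glycolysis genes fell (median -2.64, adjusted p = 0.00038), among them the glucose transporter Slc2a1 by 16.5-fold, Aldoc by 10.6-fold and hexokinase Hk2 by 8.62-fold. All 18 cholesterol synthesis genes fell (median -2.20, adjusted p = 0.000241), including Msmo1 by 13.3-fold, Cyp51 by 10.3-fold and Sqle by 9.63-fold. Of 37 S phase genes 36 fell (median -1.98, adjusted p = 1.1e-05), with Atad2, a chromatin ATPase, 12.1-fold lower, and Cdca7 rose 1.47-fold. Of 55 nuclear-encoded respiratory chain genes 49 fell (median -1.65, adjusted p = 1.47e-05), such as Ndufs4, at least 6.97-fold lower, while Atp5a1 rose 1.21-fold. Of 21 pigmentation genes 20 fell (median -1.62, adjusted p = 0.000278), among them the copper pump Atp7a by 7.42-fold and the melanosome receptor Gpr143 by 6.08-fold. The small rises of Cdca7 and Atp5a1 turned to falls when arrays were centred on background genes. Apart from the proteasome, these counts were the same when adjusted over the list alone. Among random lists of genes matched on mean level, the medians of the 7 lists lay between percentile 0 for glycolysis and chaperones and 1.06 for pigmentation. The mean used for matching includes the exosome values. By cell level alone, the median log2 fold change was -1.75 for genes at log2 9 to 10 and -1.68 at 11 to 12. The respiratory chain (median cell level 9.77) and pigmentation (11.49) lists fell no more than these, and the proteasome (9.67) little more. Chaperones, glycolysis, cholesterol synthesis and S phase genes fell further than genes of their cell level. With only signals above background in at least 1 group, a filter chosen in advance, the calls of the chaperones (adjusted p = 0.016) and the proteasome (0.0362) held, while those of glycolysis (0.0548), S phase (0.0548), pigmentation (0.0548), cholesterol synthesis (0.0636) and the respiratory chain (0.0796) ended. The background genes moved the opposite way to all 7.

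Genes of cell division, splicing and further groups fell as well, with calls under each scaling. Of 44 G2 and M phase genes 41 fell and 2 rose (median -2.41, adjusted p = 3.86e-06, and 0.281 with an estimated correlation), with Hmmr, a spindle protein, at least 4.93-fold lower. The call of the G2 and M phase list held with only signals above background in at least 1 group (adjusted p = 0.0362) and ended among genes above background in both groups (0.175). Of 56 spliceosome genes 52 fell and 2 rose (median -1.96, adjusted p = 1.4e-05, and 0.281 with an estimated correlation), with Snrpb2 9.58-fold and Prpf8 7.88-fold lower and Lsm11 2.48-fold higher. Of 68 mitochondrial ribosomal proteins 62 fell (median -1.75, adjusted p = 3.86e-06, and 0.281 with an estimated correlation), with Mrpl36 8.13-fold and Mrpl3 7.64-fold lower. Of 33 exosome biogenesis and tetraspanin genes 28 fell and 1 rose (median -1.76, adjusted p = 0.00058, and 0.281 with an estimated correlation), and 2 rose when adjusted over the list alone. Among them the tetraspanin Cd151 was 7.99-fold lower. Of 19 tubulin and actin cytoskeleton genes 18 fell and 1 rose (median -1.35, adjusted p = 0.00262, and 0.281 with an estimated correlation), with the actin crosslinker Actn1 6.00-fold lower. Of 21 interferon response genes 20 fell (median -1.71, adjusted p = 0.0011, and 0.281 with an estimated correlation), with Rsad2, an antiviral enzyme, 6.98-fold lower and Ddx58, a sensor of viral RNA, at least 7.67-fold lower. Among matched random lists the cytoskeleton median lay at percentile 13.1 (matched median -0.99), while the other lists lay between 0 for G2 and M phase and the spliceosome and 1.78 for mitochondrial ribosomal proteins. By cell level alone, without exosome values, genes at log2 9 to 10 had a median of -1.75. The exosome biogenesis list (median cell level 9.73) lay close to this, and the cytoskeleton list (9.85) fell less. The other lists fell further than genes of their cell level, such as mitochondrial ribosomal proteins (-1.75 beside -1.58) and interferon genes (-1.71 beside -1.21). With only signals above background in at least 1 group, the calls of the mitochondrial ribosomal (adjusted p = 0.0632), spliceosome (0.0918), exosome biogenesis (0.107), interferon (0.171) and cytoskeleton (0.196) lists ended. Among genes above background in both groups they ended too, except that too few interferon genes were left there to be tested.

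A further 6 lists were called lower as deposited but not after cyclic loess or with only signals above background in at least 1 group. Of 47 translation factors 43 fell and 1 rose (median -1.29, adjusted p = 7.51e-05, and 0.287 with an estimated correlation), with Eif2a 5.96-fold lower and Eif4ebp2, an inhibitor of cap-dependent translation, 5.38-fold higher. Of 113 regulators of small GTPases and membrane trafficking 85 fell and 7 rose (median -1.33, adjusted p = 0.000427, and 0.384 with an estimated correlation), with Rab5a, a GTPase of early endosomes, at least 10.1-fold lower and Snx25 2.45-fold higher. Of 211 zinc finger genes 157 fell and 19 rose (median -0.95, adjusted p = 0.00849, and 0.454 with an estimated correlation), with Zfp948 at least 5.69-fold lower and Zfp652 4.55-fold higher, and 158 fell when adjusted over the list alone. Relative to the genes tested, the zinc finger median turned from -0.56 to 0.22 with only signals above background in at least 1 group and to 0.54 among genes above background in both groups, and the call also ended after quantile normalization (adjusted p = 0.942) and centring on background genes (0.0968). Of 23 immediate early genes 20 fell (median -1.32, adjusted p = 0.00804, and 0.313 with an estimated correlation), with Atf3, a stress-induced transcription factor, 7.93-fold lower. Of 17 cytosolic heat shock chaperones 14 fell and 1 rose (median -1.44, adjusted p = 0.0149, and 0.311 with an estimated correlation), with Cct8 6.73-fold lower, and 15 fell when adjusted over the list alone. Of 21 p53 target and apoptosis genes 16 fell and 1 rose (median -0.95, adjusted p = 0.0478, and 0.362 with an estimated correlation), with Casp8 5.82-fold lower, and the median of this list turned positive after quantile normalization (0.13) and cyclic loess (0.17). Among random lists matched on mean level, the medians lay at percentile 10.3 for heat shock chaperones, 12.3 for trafficking, 23.9 for zinc fingers, 36.1 for immediate early genes, 38.3 for translation factors and 79.8 for p53 targets. After quantile normalization the calls of the trafficking (camera adjusted p = 0.0699), immediate early (0.165) and p53 (0.864) lists ended too. Centring on background genes ended that of the heat shock chaperones (0.0798). The call of the p53 list also ended without cells replicate 4 (adjusted p = 0.0563) and without exosomes replicate 2 (adjusted p = 0.0645).

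The lists of immune modulators, phosphatases, antigen presentation, matrix, histone and cytosolic ribosomal genes were not called, and most of their called members fell. Of 29 secreted and surface immune modulators 12 fell and 4 rose (median -0.08, mean -0.67, adjusted p = 0.469), with the galectin Lgals9 8.69-fold, Vegfa 5.18-fold and the surface protein Cd47 5.15-fold lower. The test placed this list above other genes, while its median and mean were negative. Of 15 phosphatases of T cell receptor and cytokine signalling 10 fell and 3 rose (median -1.09, adjusted p = 0.529), with Dusp1 5.37-fold and Ptpn12 5.06-fold lower beside the rise of Ptpn11. Of 13 antigen presentation genes 8 fell (median -0.58, adjusted p = 0.248), with B2m, the light chain of class I molecules, 6.83-fold and Tapbp 5.65-fold lower. Of 37 extracellular matrix and adhesion genes 26 fell and 4 rose (median -1.20, adjusted p = 0.0661), with the integrins Itgav and Itgb1 11.4-fold and 11.1-fold lower, and this list was called after centring on background genes (adjusted p = 0.0284). Of 12 replication-dependent histone genes 5 fell and 1 rose (median -0.96, adjusted p = 0.817), with H1f2 11.4-fold lower. The histone median lay at percentile 0.99 among random lists matched on mean level, whose own median was -0.09, although camera did not call the list. The medians of the immune modulators, phosphatases, antigen presentation, matrix and cytosolic ribosomal lists lay at percentiles 33.0, 43.0, 21.0, 22.9 and 33.8. Of 21 cytosolic ribosomal protein genes 12 fell and 1 rose (median -0.43, adjusted p = 0.993), and 14 fell when adjusted over the list alone. Only 12 of the 21 were above background in cells and 10 in exosomes. The gene that rose, Rpl39l, was above background on no array. Rpl4, Rpl31 and Rplp0 were called lower without being above background in cells. The median of the ribosomal list turned positive after quantile normalization (0.10) and cyclic loess (0.20), and its test placed it above other genes. Ribosomal protein genes have many pseudogenes of near-identical sequence, whose effect on these values was not tested.

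Markers of other cell types were mostly at background in both groups, and the background genes rose. Of 19 leukocyte markers 2 were above background in cells and 0 in exosomes, and 6 rose and 1 fell (median 0.17, adjusted p = 0.0018, and 0.281 with an estimated correlation), with 5 rising when adjusted over the list alone. Of 11 keratinocyte markers 1 was above background in cells and 0 in exosomes, and 1 rose, or 0 adjusted over the list alone (median 0.18, adjusted p = 0.00916, and 0.281 with an estimated correlation). Of 12 fibroblast markers 2 rose and 3 fell (median 0.08, mean -0.21, adjusted p = 0.134), with 1 rising when adjusted over the list alone, and Postn was at least 1.13-fold lower. Of 11 endothelial markers 1 fell, the surface glycoprotein Eng by 5.65-fold (list median 0.08, mean -0.17, adjusted p = 0.0707), and this list was called higher without cells replicate 2 (adjusted p = 0.0492). Of 8 erythroid and platelet markers 1 rose and 2 fell (median 0.10, mean -0.09, adjusted p = 0.134), and 0 rose when adjusted over the list alone. Among random lists matched on mean level, whose medians were 0.12 and 0.083, the leukocyte and keratinocyte lists lay at percentiles 75.8 and 80.2, and the fibroblast, endothelial and erythroid lists lay at 58.5, 48.1 and 73.0. The calls of the leukocyte and keratinocyte lists ended after quantile normalization (adjusted p = 0.214 and 0.249) and cyclic loess (0.479 and 0.399). The medians of these 5 lists turned negative when arrays were centred on background genes, and those of the fibroblast, endothelial and erythroid lists also after cyclic loess. Of 841 chemosensory receptor genes 330 rose and 7 fell (median 0.48, adjusted p = 3.81e-27, and 0.00101 with an estimated correlation), and 293 rose and 5 fell when adjusted over the list alone. Of 31 lists tested, 22 were called, 19 lower and 3 higher, and the background list was the only call with an estimated correlation.

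Some lists had too few measured members to be tested. Of 4 small nucleolar RNA host genes 3 fell, with Gas5, a growth arrest transcript, 2.30-fold lower as deposited and of the opposite sign after quantile normalization (log2 fold change 0.13) and cyclic loess (0.25). Airn, an imprinted noncoding RNA that lies opposite the gene Igf2r, was the only measured member of the nuclear-retained RNAs and rose 5.00-fold (log2 fold change 2.32 ± 0.14 SE, n = 4 arrays per group, limma adjusted p = 8.9e-07). Mitochondrially encoded genes and small structural RNAs had 0 measured members with a single symbol and were not analysed here.

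**Figure D3:**
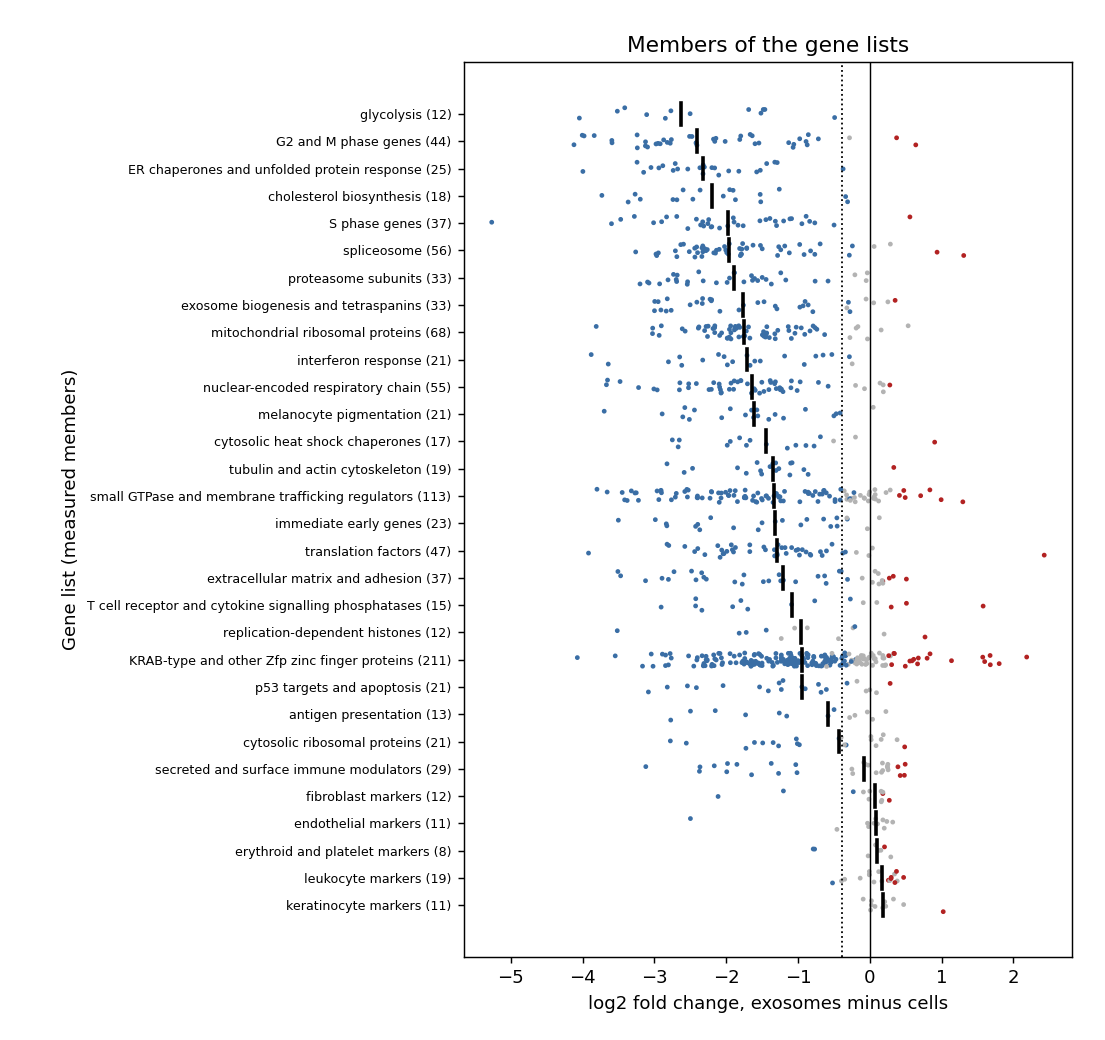
Log2 fold change between exosomes and cells (horizontal axis) of each measured member of the tested gene lists (points, red called higher, blue called lower, grey not called), with list medians as black bars, the median of all genes (-0.39) as a dotted line and the background list left out. As deposited, the medians run from -2.64 for glycolysis to 0.18 for keratinocyte markers, and those of the p53 and cytosolic ribosomal lists turn positive after quantile normalization and cyclic loess, while the positive medians of the marker lists turn negative after centring on background genes, and those of fibroblast, endothelial and erythroid markers also after cyclic loess.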

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

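None of the tests of outlying values was chosen after the results were seen. In each group of 4 values, the highest or lowest array was compared by Dixon's test with the others, and 15 of 392 groups, or 3.83%, held a value that stood apart, where chance gives about 1 in 20 groups. Of the 15 values, 11 came from cell arrays and 4 from exosome arrays. No technical or biological explanation was tested for them.

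On cells replicate 1, Lgals3bp had a log2 value of 12.5 beside 12.34 to 12.35 on the other cell arrays, Mrpl3 one of 9.93 beside 10.03 to 10.05, and the histone gene H2bc21 one of 7.50 beside 7.19 to 7.23. On cells replicate 2, Rplp0 was at 5.64 beside 5.83 to 5.87, Chmp2a at 8.36 beside 8.49 to 8.51, and the median of the mitochondrial ribosomal proteins at 8.46 beside 8.58 to 8.60. On cells replicate 4, Ptpn11 was at 10.21 beside 10.10 to 10.11, Psmd12 at 10.10 beside 9.95 to 9.96, H4c14 at 8.84 beside 9.34 to 9.44, Adgre1 at 3.68 beside 3.78 to 3.80, and the median of the erythroid and platelet markers at 5.50 beside 5.66 to 5.68.

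Among exosome arrays, Rsad2 was at 6.81 on replicate 1 beside 6.59 to 6.62 on the others, and Zfp652 at 10.60 on replicate 2 beside 10.65 to 10.66. On exosomes replicate 3, Psma6 was at 7.50 beside 7.09 to 7.14 and Cd68 at 6.67 beside 6.31 to 6.34.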

How the results depend on the processing

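The 2 restrictions to named genes above background in both groups were chosen only after the results were seen. The count of calls, 13826, stayed within 1.5 times under each alternative run, with 12998 to 13506 when 1 array was left out, and the 2-fold count with 8361 to 8592, but 3077 genes passed 2-fold among named genes above background in both groups, where fewer were tested. Of the 35 splits of the 8 arrays into 4 and 4, only the real split gave as many calls. The highest count of any other was 0 (885 against 14649 at an unadjusted limma p under 0.05). The 2-fold count behaved alike (8523 against 0, and 257 against 8569 unadjusted). A share of 1 in 35 is the smallest that this test can give. Every other split mixes cell and exosome arrays, which widens the spread within its groups, so few calls follow there. The arrays thus separated by group. The splits cannot exclude a difference between single cultures or preparations, since samples of a group may not come from separate cultures. A similar count did not mean the same calls. Of the 13826 calls, 9852 were made the same way after quantile normalization, 9242 after cyclic loess and 11070 after centring on background genes. The opposite way were 1438, 1824 and 554. Of the 8523 clusters called at 2-fold, 7066 were called the same way after quantile normalization, 6729 after cyclic loess and 8237 after centring on background genes, and 124, 282 and 0 the opposite way. Signal over background, 2.92 in exosomes against 4.91 in cells on the log2 scale, limits the exosome values.

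The number of called lists, 22, was 21 to 23 when 1 array was left out, 14 after cyclic loess, 4 with only signals above background, 8 among genes above background in both groups and 1 with an estimated correlation. Genes above background numbered 4167 in cells, 1949 in exosomes and 982 in both by the test that the series text names, run on background genes in place of control probesets, at its stricter limit, 11968 in exosomes and 11931 in both at its looser limit, and 3248 and 3240 at the 99th percentile. The correlation of mean levels was 0.702 with only signals above background and 0.907 after quantile normalization. The cause was not tested for these.

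The replicate number as a block gave 13227 calls, 8492 at 2-fold and 21 lists, and no pairing was seen: deviations of equal numbers correlated at -0.05, 0.00, -0.03 and -0.01, and 0 cell arrays correlated best with their own number. The block ended the call of 4 of the 161 named gene results. Without a turn of sign, such calls also ended for 9 after cyclic loess, 7 after quantile normalization and 4 after centring on background genes. The trended and robust prior ended 3, array weights ended 1, and the runs that left out 1 array ended 33 in total. The block also ended the call of the p53 list (camera adjusted p = 0.0579). It turned the direction of the test of the cytosolic ribosomal list, whose relative median of -0.043 it did not move. Leaving out 1 array turned that direction in 4 of 8 cases, with relative medians of -0.097 to -0.042 over the 8.

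Where the direction of a list's test turned, its median relative to all genes is given. Relative medians of unchanged sign were those of the histones after centring on background genes (-0.57), zinc fingers after cyclic loess (-0.087), and phosphatases with only signals above background (-0.45) and with the restriction to both groups (-0.23). The sign changed as well for immune modulators (-0.13 after quantile normalization, -0.12 after loess, -0.61 with only signals above background), p53 targets (0.10 after quantile normalization, 0.15 after loess), zinc fingers (0.22 with only signals above background, 0.54 with the restriction to both groups), and fibroblast (-0.034) and endothelial markers (-0.085) after loess. Centring on background genes lowered every exosome value relative to the cell values, which turned small rises to Rpl39l -0.11, Atp5a1 -0.31, Cdca7 -0.034, Chmp1a -0.24, Cd200 -0.10, Col5a2 -0.083, Fas -0.31, Tuba4a -0.26, Adgre1 -0.12, Itgam -0.22, S100a9 -0.24, Ptprc -0.29, Col3a1 -0.32, Col1a1 -0.41 and Itga2b -0.39. Gas5 turned to 0.13 after quantile normalization and 0.25 after loess, and Cd68 to 0.42 and 0.42.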

Other observations

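The tests of normalization and of a weaker signal alike for all genes, and the genes named in the next paragraph, were chosen only after the results were seen.

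Beyond the genes already described, regulators of transcription and RNA were among the 195 genes above background in both groups that rose at least 2-fold. Elk4, a transcription factor that works with serum response factor, rose 7.13-fold (log2 fold change 2.83 ± 0.08 SE, n = 4 arrays per group, limma adjusted p = 3.66e-08), and G3bp1, an RNA-binding protein of stress granules, rose 6.27-fold (2.65 ± 0.11). Zmat3, an RNA-binding target of p53, rose 5.60-fold, Rbfox2, a splicing regulator, 4.16-fold, and Ago2, the slicer protein of RNA interference, 3.10-fold. Tet3, which oxidises methylated DNA, rose 4.10-fold, Cic, a transcriptional repressor, 3.68-fold, and the cell cycle factors E2f1 and E2f2 rose 3.75-fold and 2.40-fold. Trak2, an adaptor of mitochondrial transport, rose 7.00-fold, Socs7, an inhibitor of cytokine signalling, 6.82-fold, and the tumour suppressors Tsc1 and Apc 2.48-fold and 2.12-fold. These are examples, and no enrichment of such functions among the rising genes was tested.

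Transcript clusters that were unnamed here held many of the rises. Of 7317 such clusters, 826 rose and 1315 fell at least 2-fold, and 17 rose more than any cluster of a single named gene. The largest rises were those of clusters 4562138 (log2 fold change 5.58 ± 0.22 SE) and 4418194 (5.46 ± 0.15), and the largest fall was that of 6951552 (-6.06 ± 0.24). In cells, clusters 4562138 and 4418194 had mean log2 values of 5.89 and 5.84, near the mean background threshold of 5.74.

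The first pattern was the 195 genes that rose at least 2-fold while most genes fell. A single background or DNA signal added to every gene is argued against for 175 of these genes. Their cell level alone exceeded the 99th percentile of the background genes in exosomes, log2 7.29, so an added signal of that size could not double them. The linear gain exceeded that level for 96.9% of the 195. A 2-fold rise forces such a gain for the 175, so this share is no further evidence. The authors' normalization stays open: 195 of 195 were called higher under each of 3 other scalings, but the genes had been chosen for a log2 change of at least 1 and centring on background genes took off 0.59, so that outcome was fixed. Gene length may contribute. The rising genes had a median genomic span of 34491 bp, against 25123 bp (21108 to 30152) for genes of matched level, at percentile 99.96 of random lists. Such a difference had been predicted before the test if span contributed. The 2882 genes that fell at least 2-fold were shorter, at 23213 bp against 25570 bp (24825 to 26409) and percentile 0. A trend with span thus ran through both directions, and its part in the rises stays open. A biological difference between cells and exosomes was not tested apart from these.

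The second pattern was the median fall of genes above background in both groups, -1.16 on the log2 scale. A weaker signal on the exosome arrays stays open. In each bin of cell level above 7 the median log2 fold change lay between -1.75 and -1.21. These bins also held genes not above background in exosomes, so their medians are not those of this pattern's genes alone. The interquartile range of at least 1.06 within these bins does not bear on what moved the median. Whether the authors' normalization set the direction cannot be told apart from a true fall. The median was 0.05 after quantile normalization, 0.18 after cyclic loess and -1.76 after centring on background genes, but quantile normalization and loess give the arrays a common distribution, so their values near 0 follow by construction. Whether these mRNAs were lower in exosomes as amounts stays open.

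The third pattern was a hypothesis that mRNAs of secreted and membrane proteins were lower in exosomes than other mRNAs of the same level, tested on gene families listed before the test. The 255 genes had a median of -0.21 relative to matched genes, at percentile 0.19 of random lists, with 211 falling and 27 rising, and 290 genes of cytosolic and nuclear families had -0.10, at percentile 4.72. Matching on genomic span as well gave -0.18, which lies between the values predicted with and without span as the cause, so span may still contribute. The size was below that predicted, camera gave p = 0.194 for the secretory families (0.747 with an estimated correlation), and the difference between the classes was not tested, so the hypothesis stays undecided.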
